A study of Mus musculus with 8 samples.

How the data were processed

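Bulk RNA-seq libraries of 2 sorted bone marrow fractions of C57BL/6 mice were compared, 4 of HSC and 4 of HPC, grouped by their titles. Per the labels' protocols, RNA was extracted with ISOGEN, cDNA was made with the SMARTer Pico kit and amplified by 18 cycles of PCR, and libraries were made with Nextera XT. Genome build mm10 was used, per the submitters' processing notes. The aligner, the read counter and whether counting used strand are not given in the sources used here. Reads from a gene and an overlapping or antisense neighbour therefore cannot be told apart.

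Each deposited file held 48737 rows for 1 library. The deposited counts are whole numbers of exon, intron, gene and exon-exon reads per row, each as a total and as uniquely placed reads, per the file headers. The deposited RPKM equals total exon reads per kilobase of exon and scaled to mapped library size, since these columns gave 1 constant for each library. The deposited TPM is scaled by the authors to a fixed sum per library. RPKM and TPM were not used for tests. Total exon reads were the measure tested. Of the exon reads, 81.5% to 85.5% were uniquely placed.

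Reads of genes that also lie on alternate loci were spread over several rows, for 1931 of 46113 NCBI gene IDs, and were summed per gene ID. Exons were given for 21991 gene IDs. The other 24122, among them 11074 long noncoding RNAs and the mitochondrial genes, had gene reads only and were tested in a separate fit on gene reads. Positions are those of the files, 1-based.

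Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default settings, libraries were scaled by TMM, and groups were compared by the quasi-likelihood F test with no covariate. Changes are HSC over HPC on the log2 scale, and the standard error given is the size of the change divided by the square root of F. Levels are TMM-normalised CPM as mean ± SD over 4 libraries, and folds are ratios of those means. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The biological coefficient of variation was 18.3%.

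The design, the 36 gene lists, the rule for named genes and a first set of alternatives were chosen before the data were examined. The lists were fixed from general knowledge, and none was chosen on these samples. Of 884 list memberships 883 matched a gene in the files, and 1 symbol (Ahsp) did not. Lists of at least 3 tested genes were tested with camera of limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted over 35 lists. For the genes named, among called genes with a mean of at least 20 CPM and fully separated groups, leaving out unnamed predicted models and small RNA or pseudogene symbols, the 6 with the largest change in each direction were taken. To these were added up to 2 called members per biological list with the smallest adjusted p (mean of at least 5 CPM), all sort markers, and the most abundant member of each technical or other cell type list. Some of the genes taken by this rule are not reported here. Further list members named as examples were chosen after their values were seen.

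On simulated counts for these 8 libraries, with 12622 genes tested and 200 changed, edgeR recovered 35 of 100 genes changed 1.5-fold and 75 of 100 changed 2-fold, and 8 of its 118 calls were false. A list shifted 1.25-fold was recovered, with 0 other lists called. Genes were drawn independently there, so this cannot show how often correlated genes give false list calls. No pair of libraries of a group looked like 1 library deposited again, with a mean chi-square per gene of 12.2 to 42.2. Median changes over 5 equal bins of exon length lay between −0.03 and 0.03.

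The first set of alternatives was RLE and upper quartile scaling, no count filter and a filter of 50 reads in 4 libraries, the replicate number as a block, voom with sample quality weights, DESeq2 1.42.0, a tested fold of 1.5, a threshold of 0.01, camera with an estimated correlation, fry, and leaving out each library. Added after seeing the data were unique exon reads, main-assembly rows only, gene reads, the share of exon-exon reads as a covariate, and leaving out both libraries numbered 4. Alternatives for normalized values were not needed, since the files hold counts.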

Results

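RNA from 2 cell fractions of mouse bone marrow was sequenced. Both fractions were sorted as lineage-negative cells carrying c-Kit, Sca1 and CD150 on their surface, and were parted by CD34. The CD34-negative fraction is named HSC in the labels, for hematopoietic stem cells, and the CD34-positive fraction HPC, for hematopoietic progenitor cells. Each fraction has 4 libraries from C57BL/6 mice of 8 to 10 weeks. The protocol given with all 8 libraries states 5000 sorted cells but speaks of HSC only. The HSC libraries held 16291733 to 19070313 exon reads and the HPC libraries 18223082 to 20564901. Exon reads were found for 14222 to 15041 genes in the HSC libraries and for 14008 to 14141 in the HPC libraries. Nothing in the labels says that the libraries came from separate animals, so p-values measure the spread between these samples, which may be technical. A library with 0 reads of a gene could still hold up to 3 reads' worth, or 0.146 to 0.184 CPM (reads scaled to library size), and such limits cover counting error only, since PCR copies of a molecule were counted as reads.

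The comparison asks which genes differ between the CD34-negative HSC fraction and the CD34-positive HPC fraction. In HSC, genes of long-term stem cells, of the erythroid lineage and of megakaryocytes were higher, and in HPC, myeloid, lymphoid and cell division genes were higher. Among 12751 genes tested, 2493 were higher in HSC and 2240 were lower at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Of these, 1392 were at least 2-fold higher and 775 at least 2-fold lower, and 754 and 281 differed by at least 4-fold. The 4 HSC libraries lay fully apart from the 4 HPC libraries for 4678 genes, 36.7% of those tested, where chance gives 2.86%. Correlations of log2 CPM across 9843 genes were 0.968 to 0.983 between libraries of a fraction and 0.849 to 0.887 between fractions, and the first principal component held 75.8% of the variance. These are correlations across genes, which are not independent replicates. With a fold of at least 1.5 required by the test, 2099 genes remained called.

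**Figure D1:**
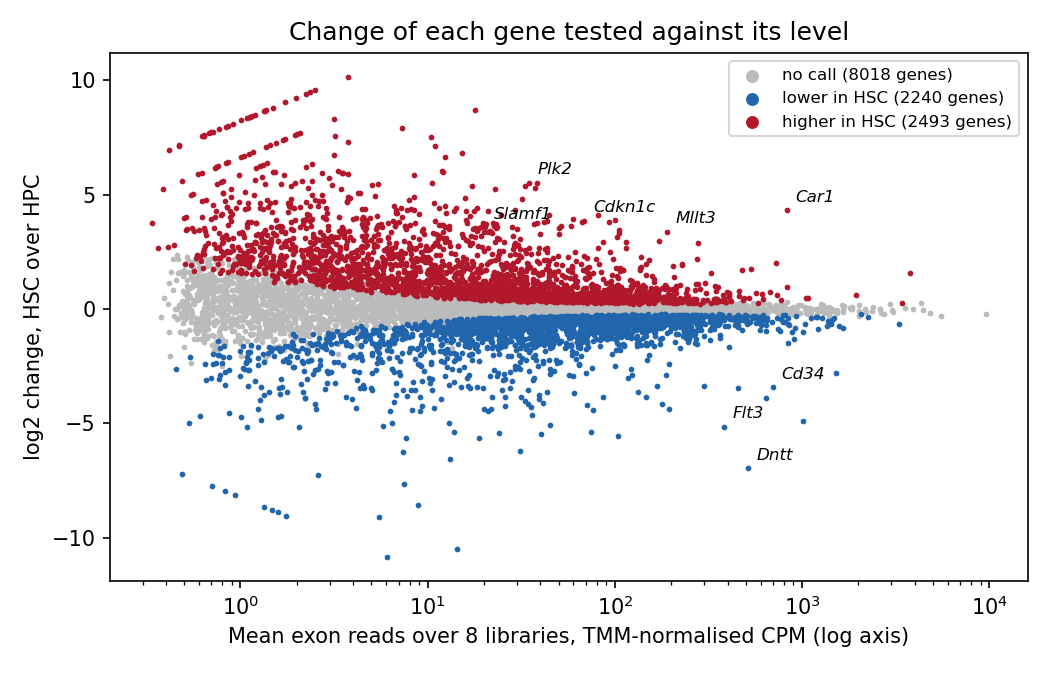
Log2 change of HSC over HPC (vertical axis) for each of the 12751 genes tested, against the mean exon reads over the 8 libraries in TMM-normalised CPM (horizontal log axis). The 2493 red points are genes higher in HSC and the 2240 blue points genes lower in HSC; Car1 lies at 4.31 and Dntt at −6.95, and the slanted lines at low CPM are genes with 0 or few reads in 1 fraction, whose fitted changes depend on the prior count.

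Among the genes of the sort markers, Cd34 went with the gate that parted the fractions. Cd34 (NCBI gene 12490, chromosome 1, 194938821 to 194961292, mm10) stood at 120 ± 15.3 CPM in HSC and 1275 ± 55.9 CPM in HPC (SD, n = 4 each), a log2 change of −3.41 ± 0.11 (SE; edgeR adjusted p = 5.7e-11). Slamf1, which encodes CD150 (gene 27218, chromosome 1, 171767132 to 171801184), was at 37.6 ± 6.02 CPM in HSC and 3.14 ± 0.735 CPM in HPC, 12.0-fold higher in HSC (log2 3.58 ± 0.20, edgeR adjusted p = 6.6e-09), although the labels give both fractions as CD150-positive. Ly6a, which encodes Sca1 (gene 110454, chromosome 15, 74994877 to 74998031), was 1.82-fold higher in HSC, at 131 ± 16.0 against 72.1 ± 8.01 CPM. Ly6a belongs to a family of similar genes, so reads shared with its relatives leave its level uncertain. Kit (gene 16590, chromosome 5, 75574987 to 75656722) was at 924 ± 185 CPM in HSC and 746 ± 66.3 CPM in HPC and did not pass the test (edgeR adjusted p = 0.080). Flt3 and Cd48, which mark progenitors and were not part of the labelled gate, were lower in HSC. Flt3 (gene 14255, chromosome 5, 147330741 to 147400489) was at 20.9 ± 3.27 against 743 ± 75.3 CPM, and Cd48 (gene 12506, chromosome 1, 171681420 to 171705257) at 19.7 ± 3.75 against 246 ± 40.0 CPM. The 6 genes went both ways, with 2 higher in HSC, 3 lower and 1 without a call. Camera gave the list the direction lower (adjusted p = 5.7e-07), which ended under voom with sample quality weights (adjusted p = 0.18), but the list holds Cd34, on which the fractions were parted, so this call is no finding of its own. With p adjusted over the list alone, 3 were higher and 3 lower.

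**Figure D2:**
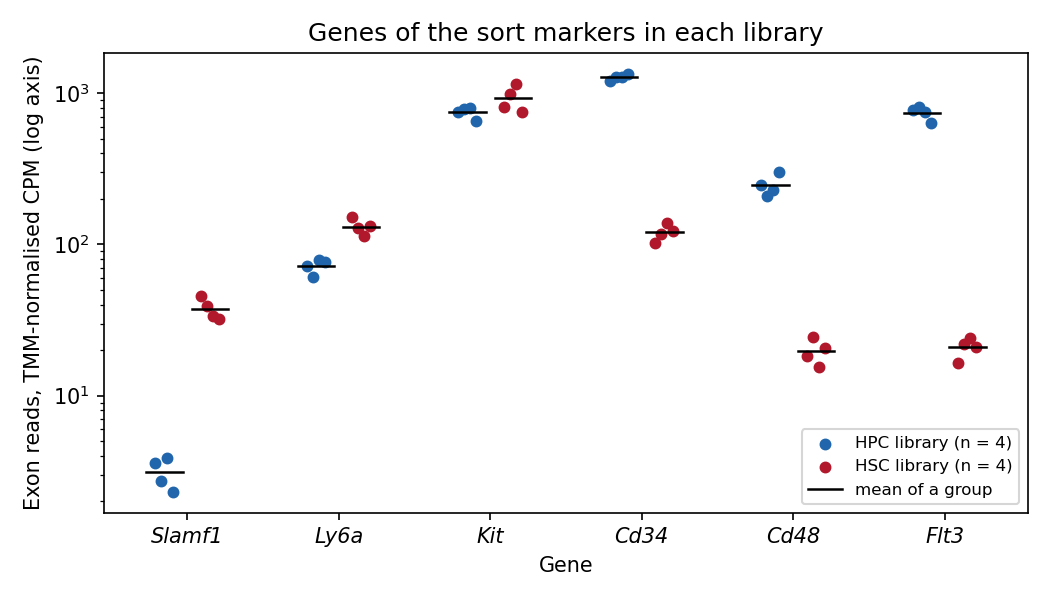
Exon reads of 6 sort marker genes in TMM-normalised CPM (vertical log axis), 1 point per library, with HPC in blue, HSC in red and the mean of each group of 4 as a black bar. Slamf1 averages 37.6 CPM in HSC and 3.14 CPM in HPC, Cd34 and Flt3 lie lower in all 4 HSC libraries, and the Kit values of the fractions overlap.

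The largest changes among genes with a mean of at least 20 CPM and fully separated fractions came from genes with varied roles. Higher in HSC were Plk2, a polo-like kinase (gene 20620, chromosome 13, 110395044 to 110400844; 68.3 ± 2.45 against 1.48 ± 0.534 CPM, log2 5.52 ± 0.21, edgeR adjusted p = 2.1e-10), and Sult1a1, a sulfotransferase (gene 20887, chromosome 7, 126672865 to 126690426; log2 5.49 ± 0.27). Tns2 (5.36), Tinagl1 (5.30) and the amino acid transporter Slc38a5 (4.31) were also among them; the change of Tns2 was 6.43 without HPC replicate 2. Lower in HSC were Dntt, the terminal transferase of antigen receptor joining (gene 21673, chromosome 19, 41029275 to 41059525; 8.30 ± 3.33 against 1026 ± 149 CPM, log2 −6.95 ± 0.26, edgeR adjusted p = 1.4e-10), and Cd244 (gene 18106, chromosome 1, 171558713 to 171585316; log2 −6.22 ± 0.39). They were followed by BC035044 (−5.54), Wfdc17 (−5.47), Emp1 (−5.41) and Tespa1 (−5.36). The change of Cd244 was −7.33 without HSC replicate 4, and that of Emp1 −6.78 without HSC replicate 3.

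Of 30 long-term stem cell genes, 29 were higher in HSC and 1, Vldlr, was lower. Their median log2 change was 2.57 (camera adjusted p = 2.3e-46, or 0.0046 with an estimated correlation). Mllt3 was at 346 ± 17.4 CPM in HSC and 33.4 ± 5.67 CPM in HPC (log2 3.37 ± 0.12). Ndn, an imprinted gene, was 11.5-fold higher (log2 3.52 ± 0.14), Mecom 5.65-fold, and Procr, which encodes the stem cell marker EPCR, 4.83-fold. Vldlr was at 5.97 ± 0.832 CPM in HSC and 41.7 ± 6.81 CPM in HPC. Of 44 transcription factors of early blood cells, 28 were higher in HSC, 8 lower and 8 without a call, with a median of 0.57 (camera adjusted p = 8.2e-06). That call was lost with an estimated correlation (adjusted p = 0.097). Hoxb5 was at 20.9 ± 1.70 against 0.843 ± 0.239 CPM, Mycn at 488 ± 17.2 against 164 ± 13.5 CPM and Nfia at 230 ± 25.4 against 47.5 ± 10.6 CPM. Runx3 (−1.74) and Sox4 (−1.18) were among those lower in HSC. Adjusted over the list alone, the stem cell counts were again 29 and 1, and those of the transcription factors 30 and 10.

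All 18 erythroid priming genes were higher in HSC, and all 18 were again so when adjusted over the list alone. Their median log2 change was 2.74 (camera adjusted p = 2.0e-31, or 0.019 with an estimated correlation). Car1, a carbonic anhydrase of early erythroid cells (gene 12346, chromosome 3, 14766214 to 14808365), was at 1581 ± 217 CPM in HSC and 79.8 ± 17.7 CPM in HPC, 19.8-fold higher (log2 4.31 ± 0.17, edgeR adjusted p = 2.4e-10). Ermap was at 188 ± 18.5 against 12.5 ± 3.34 CPM. Klf1, an erythroid transcription factor, was 10.1-fold higher, and Epor, the erythropoietin receptor, 6.90-fold. Red cell markers moved with this group, as 5 of 9 were higher in HSC and 4 had no call, at a median of 1.96 (camera adjusted p = 0.0085, and adjusted p = 0.34 with an estimated correlation). The globin gene Hba-a1 was at 105 ± 56.1 against 26.9 ± 21.9 CPM. Without HPC replicate 1 the change of Hba-a1 went from 1.96 to 2.62 and the median of the red cell markers to 2.70. Reads of Hba-a1 and Hba-a2, like those of Hbb-bs and Hbb-bt, may have been split between near-identical copies. For red cell markers 8 were higher when adjusted over the list alone.

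Megakaryocyte and platelet genes were higher in HSC for 13 of 18, lower for 1 and without a call for 4. Their median was 1.03 (camera adjusted p = 2.3e-06, or 0.019 with an estimated correlation). Vwf, the von Willebrand factor, was at 77.6 ± 18.4 against 5.54 ± 0.782 CPM, and Clu was 11.8-fold higher. Itga2b was slightly lower (log2 −0.29 ± 0.11, edgeR adjusted p = 0.049), and Pf4 had no call at 54.9 ± 17.4 against 62.0 ± 18.8 CPM. When adjusted over the list alone, 14 were higher and 1 lower.

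Myeloid priming genes were lower in HSC for 20 of 22, with none higher. Their median was −2.43 (camera adjusted p = 4.5e-20, or 0.040 with an estimated correlation). Mpo, the myeloperoxidase of granules, was at 65.8 ± 47.4 CPM in HSC and 1946 ± 403 CPM in HPC, and Cebpa at 1.82 ± 1.45 against 40.0 ± 5.48 CPM. Without HSC replicate 2 the log2 changes went from −4.89 to −5.53 for Mpo and from −4.44 to −5.17 for Cebpa. Cd33 had 3 reads over the 4 HSC libraries, all in replicate 1, and 1328 over the 4 HPC libraries. Markers of mast cells, basophils and eosinophils moved with this group. Of 10 such markers, 8 were lower in HSC and 2 had no call (median −3.31, unchanged with the 2 genes at 0 set to a floor of 3 reads per library; camera adjusted p = 3.4e-06, and adjusted p = 0.097 with an estimated correlation). Cpa3 was at 2.58 ± 0.927 against 49.3 ± 4.83 CPM and Prss34 at 11.6 ± 12.3 against 65.7 ± 42.8 CPM. Without HSC replicate 3 the median of these markers was −4.42 and the change of Prss34 went from −2.50 to −3.51. Both counts, 20 and 8, were again found when adjusted over the list alone.

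Lymphoid priming genes were lower in HSC for 14 of 19, higher for 2 and without a call for 3. Their median was −1.47 (camera adjusted p = 4.1e-16, or 0.0055 with an estimated correlation). Besides Dntt and Wfdc17, the lower genes included Satb1, a chromatin organiser, 14.4-fold lower. Rag2, a recombinase subunit, was at 0.806 ± 0.343 against 25.3 ± 3.69 CPM. Igll1 (7.07-fold) and Lef1 (4.01-fold) were higher in HSC. B cell markers and T and NK cell markers gave no list call. Of 8 B cell markers, 4 were higher in HSC and 1 lower (camera adjusted p = 0.21), with the most abundant, Cd79b, without a call (log2 −0.03 ± 0.11). Of 11 T and NK cell markers, 7 were higher and 1, Nkg7, was lower, at 44.6 ± 8.39 against 330 ± 40.8 CPM (camera adjusted p = 0.31). Adjusted over the list alone, the counts higher and lower were 2 and 14 for the lymphoid priming genes, 5 and 1 for B cell markers and 8 and 1 for T and NK cell markers.

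Cell division genes were lower in HSC. Of 40 genes of G2 and M phase, 39 were lower and Cenpa had no call. Their median was −1.10 (camera adjusted p = 2.3e-26, or 0.030 with an estimated correlation). Nusap1 was at 74.2 ± 3.86 against 221 ± 16.9 CPM, Ect2 was 3.83-fold lower, and Top2a was at 194 ± 25.2 against 616 ± 132 CPM. Of 38 S phase genes, 36 were lower, Chaf1b had no call and Ccne1, a cyclin of S phase entry, was 3.21-fold higher, with a list median of −0.77 (camera adjusted p = 2.5e-14, and adjusted p = 0.097 with an estimated correlation). Hells was 2.42-fold lower. Of 34 DNA damage repair genes, 22 were lower and 12 had no call. Their median was −0.61 (camera adjusted p = 3.1e-06, or 0.049 with an estimated correlation). Rad54b was 3.16-fold lower. CDK inhibitors and cell cycle brakes gave no list call (3 higher, 7 lower, 7 without a call, median 0.00, mean −0.09, camera direction lower, adjusted p = 0.74). Among them Cdkn1c, which encodes p57 and is imprinted, was 14.5-fold higher at 129 ± 7.34 against 8.87 ± 1.88 CPM, and Cdkn2c was 2.57-fold lower. The counts lower, adjusted over the list alone, were 40, 36, 24 and 7 for the 4 lists in this order, and those higher 0, 1, 0 and 4.

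Interferon-stimulated genes were higher in HSC for 16 of 32, lower for 4 and without a call for 12 (median 0.35, camera adjusted p = 0.022, and adjusted p = 0.36 with an estimated correlation). The list call also ended when only uniquely placed exon reads were counted, a setting chosen after seeing the data (camera adjusted p = 0.059). Iigp1 was 3.51-fold higher, and Ifi27 was 2.20-fold lower. Of 29 cytokine and growth factor receptor genes, 9 were higher, 13 lower and 7 without a call. The list was called lower (camera adjusted p = 0.022) at a median of only −0.03 and a mean of −0.43, and the call ended with an estimated correlation (adjusted p = 0.43) and under voom with quality weights (adjusted p = 0.24). Pdgfrb was at 5.43 ± 1.19 CPM in HSC and 73.6 ± 7.21 CPM in HPC. Adjusted over the list alone, 16 interferon-stimulated genes were higher and 4 lower, and 11 receptor genes were higher and 13 lower.

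**Figure D3:**
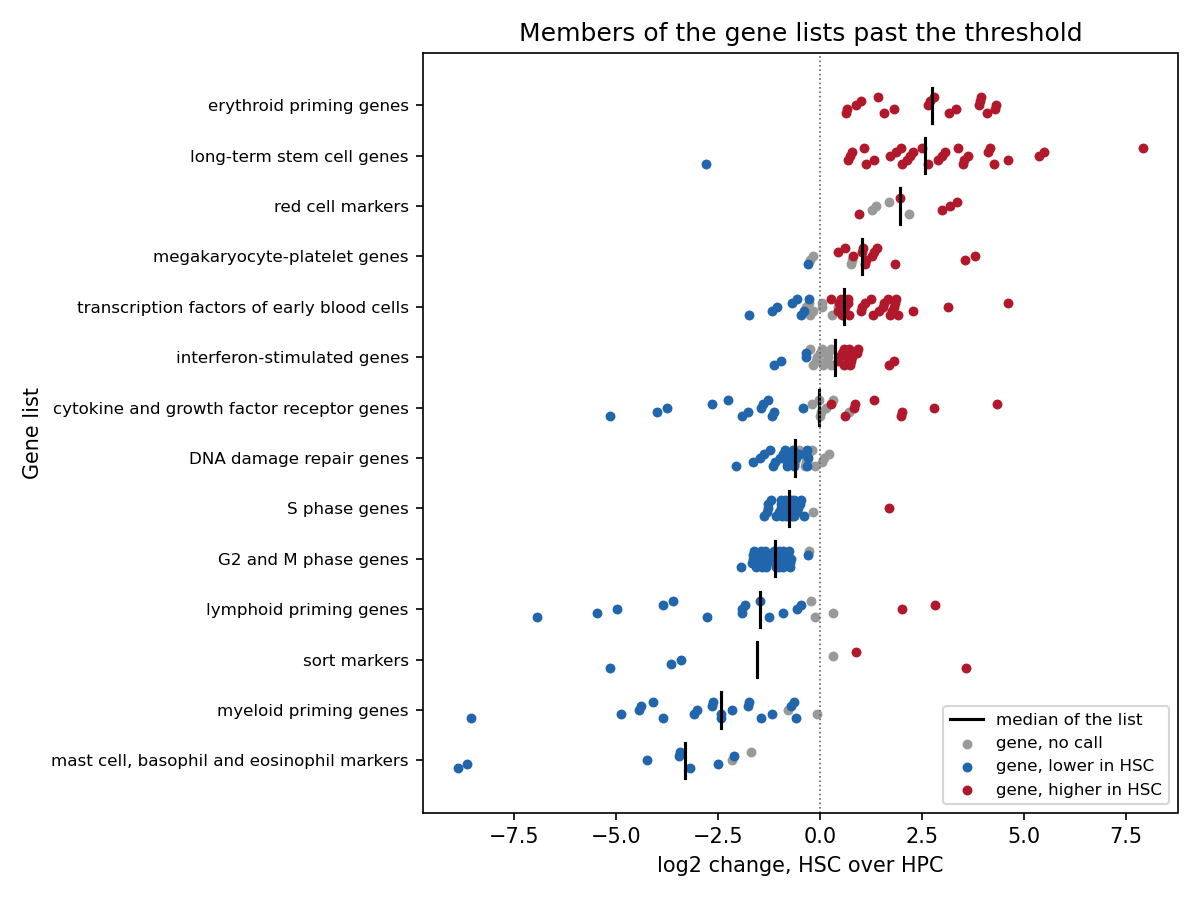
Log2 change of HSC over HPC (horizontal axis) for each tested member of the 14 gene lists past the threshold (vertical axis), red where higher in HSC, blue where lower and grey without a call, with the list median as a black bar. The erythroid list has the highest median at 2.74 with all 18 genes to the right of 0, and the mast cell, basophil and eosinophil list the lowest at −3.31, where the points farthest left are genes with 0 reads in HSC.

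In all, 14 of 35 lists passed the threshold, 6 higher and 8 lower in HSC, and 8 of them also did so with an estimated correlation. Both counts include the list of sort markers, which holds Cd34. Other splits of the 8 libraries gave up to 21 lists with the preset correlation and up to 1 with an estimated one. The lists for the machinery of protein synthesis and respiration gave no call. None of 57 cytosolic ribosomal protein genes was called by edgeR, DESeq2 or voom, with 0, 3 and 1 at an unadjusted p under 0.05 (edgeR median 0.00, camera adjusted p = 0.77). By edgeR 1 of 44 ribosome biogenesis genes was called, Heatr1, which was lower in HSC (edgeR adjusted p = 0.042; camera adjusted p of the list = 0.60). Heatr1 lost that call without HPC replicate 1 or 3 and without each HSC replicate, with log2 changes over the fits that left out 1 library from −0.74 to −0.39. Of 53 respiratory chain genes Ndufb9 was higher (1.27-fold) and 2 were lower, Ndufa4 (2.44-fold) and Cox5a (1.40-fold; camera adjusted p of the list = 0.61). Of 11 mitochondrially encoded genes, tested on gene reads because they have no exon counts, 0 were called by edgeR and 0 had an unadjusted p under 0.05 (median −0.06). TCA cycle genes were lower for 6 of 22, such as Idh2 (2.01-fold; camera adjusted p of the list = 0.24), and glycolysis genes went both ways (6 higher, 7 lower, 9 without a call), with Pgam1 1.93-fold lower and Aldoc 2.66-fold higher. The glycolysis list had a median of −0.12 and a mean of 0.33, the latter raised by Pdk4 with 0 reads in HPC, while camera gave the direction lower (adjusted p = 0.68). The counts higher and lower, adjusted over the list alone, were 0 and 0 for ribosomal protein genes and for ribosome biogenesis genes, 0 and 2 for respiratory chain genes, 0 and 4 for TCA cycle genes and 6 and 8 for glycolysis genes.

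MHC class II genes also went both ways, with 4 of 11 higher in HSC, such as H2-Aa at 56.5 ± 2.37 against 17.4 ± 2.94 CPM, and 5 lower, such as H2-Ob at 7.35 ± 2.86 against 135 ± 17.0 CPM. Their median was 0.14 and their mean −0.15, and camera gave the direction lower (adjusted p = 0.68). Adhesion and homing genes were higher for 10 of 27 and lower for 9, with Esam 4.64-fold higher, a median of 0.01, a mean of −0.18 and the camera direction lower (adjusted p = 0.68). Of 26 DNA methylation and Polycomb genes 2 were higher and 10 lower, with Cbx7 2.62-fold higher and Cbx2 2.48-fold lower (camera adjusted p = 0.11). Higher in HSC were 12 of 25 antioxidant genes (Srxn1, 3.38-fold; Nqo1, 3.32-fold; 2 lower), 10 of 22 TGF-beta and BMP pathway genes (Tgfbr3, 3.44-fold; Eng, 2.04-fold; 2 lower), 10 of 22 cholesterol synthesis genes (Insig1, 1.86-fold; Stard4, 1.70-fold; 2 lower) and 7 of 33 autophagy and lysosome genes (Gabarapl1, 1.87-fold; Ctsl, log2 1.59 ± 0.15). The camera adjusted p of these 4 lists was 0.064, 0.067, 0.11 and 0.19. Of 20 p53 targets 3 were higher, Plk2 among them, and 6 lower, such as Psrc1 (2.92-fold; camera adjusted p = 0.78). By list, the counts higher and lower adjusted over the list alone were 4 and 5 for MHC class II, 10 and 10 for adhesion, 2 and 10 for DNA methylation and Polycomb, 13 and 3 for antioxidant, 10 and 2 for TGF-beta and for cholesterol, 7 and 0 for autophagy and 3 and 6 for p53 target genes.

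Immediate early genes, which handling of cells can induce, were higher in HSC for 9 of 22 and lower for 2 (median 0.63, camera adjusted p = 0.19), with Ier2 at 381 ± 63.6 against 233 ± 48.7 CPM. Heat shock genes were higher for 1 of 11 and lower for 1, and Hspa8 had no call at 4561 ± 706 against 5115 ± 352 CPM (camera adjusted p of the list = 0.94). Lyz2, the most abundant neutrophil and monocyte marker, had no call at 191 ± 32.9 against 262 ± 72.4 CPM. Neutrophil markers were higher for 1 of 9 and lower for 1 (camera adjusted p = 0.61), and monocyte, macrophage and dendritic markers were lower for 3 of 14 (camera adjusted p = 0.20). Of 9 stromal and endothelial markers 4 were higher and 2 lower, with Tie1, which stem cells also express, at 170 ± 21.7 against 52.1 ± 1.97 CPM. Their median was 1.12, while camera gave the direction lower (adjusted p = 0.99). Counts higher and lower, adjusted over the list alone, were 10 and 2 for immediate early genes, 1 and 0 for heat shock genes, 1 and 1 for neutrophil, 0 and 3 for monocyte and 4 and 2 for stromal markers.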

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

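The tests of Slamf1 and 2 of the 3 tests of the erythroid genes below (globin level, and shared rise and fall) were chosen only after the results were seen. In 222 groups of 4 libraries, 8 had a library whose gap to the others exceeded Dixon's critical value, where chance gives about 1 in 20, or 11.1. Cd244 was at 2.11 CPM in HSC replicate 4, against 0.261 to 0.536 in the other HSC libraries. Cd33 was at 0.179 CPM, or 3 reads, in HSC replicate 1 and at 0 in the others, where any nonzero value would have been flagged. Insig1 was at 91.5 CPM in HPC replicate 2, against 59.4 to 64.0 in the others, and HSC replicate 2 was also the highest of its group, at 146 against 120 to 127. Mycn was at 144 CPM in HPC replicate 1, against 170 to 173. The mean log2 CPM of the myeloid priming genes was 3.92 in HSC replicate 2, against 3.25 to 3.29, still below the HPC mean of 6.02. That of the heat shock genes was 7.77 in HPC replicate 3, against 6.66 to 6.75, and HSC replicate 3 was also the highest of its group, at 7.61 against 6.44 to 6.91. That of the mast cell, basophil and eosinophil markers was 1.19 in HSC replicate 3, against −1.09 to −0.758. Intron reads made up 15.7% of gene reads in HSC replicate 4, against 19.4% to 19.6% in the other HSC libraries, and HPC replicate 4 was also the lowest of its group, at 16.4% against 17.7% to 20.6%.

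Outside the exon reads, gene reads without annotated exons made up 5.91% of gene reads and introns of genes with exons 18.4%, as means over 8 libraries. On gene reads, 502 genes without exons were called by edgeR, 341 higher and 161 lower in HSC. Of 1703 long noncoding RNAs tested, 282 were higher and 113 lower.

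Whether an arbitrary grouping of the libraries could give as many calls was tested by refitting all 35 splits of the 8 libraries into 4 and 4. The real split gave 4733 genes and the highest of the others 2, so that 1 of the 35 splits, the real one, gave as many. This argues against an arbitrary grouping, but 1 of 35 is the smallest share these splits can give. Mixing the fractions in the other splits also widens the spread within their groups, which can lower their counts. Chance is therefore not excluded more firmly than that share. For lists with the preset correlation the count says less. The real split gave 14 lists and another gave 21, and 15 of the 35 splits gave at least 14, so chance cannot be excluded for that count. The 16 splits with 3 libraries of a fraction against 1, which keep part of the difference between the fractions, gave 12 to 21 lists. The 18 splits with equal shares of both fractions gave 1 to 9. With an estimated correlation the real split gave 8 lists and the highest other 1, so that only 1 of the 35 splits gave as many. In the other splits the difference between the fractions enters the residuals from which the correlation is estimated. That can lower their counts, and the 16 splits of 3 against 1 all fell to 0 lists. This count therefore cannot exclude chance for the lists apart from the difference in genes.

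Slamf1 RNA was 12.0-fold lower in HPC, although both gates were labelled CD150-positive. Reads shared with other places in the genome are argued against, since the log2 change was 3.58 on unique exon reads. An HPC gate that also held CD150-negative cells stays open. Lymphoid priming genes were higher in HPC (camera adjusted p = 4.1e-16), as such a gate would need, but this was known when the test was chosen and does not separate a wide gate from CD150-positive progenitors that carry lymphoid genes, or from surface protein that outlasts its RNA. No protein was measured here.

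Erythroid genes were higher in HSC for 18 of 18. Mature red cells or their free RNA are argued against, since the 4 adult globin genes together reached at most 0.275 of the level of Car1 in any HSC library. Erythroid progenitors, which the lineage and Sca1 gates should remove, may account for part of it. Heme synthesis genes were higher in HSC for 8 of 12 and lower for 2. Further genes of erythroid colony-forming progenitors were higher for 14 of 17 and lower for 1. The most abundant of these, Atpif1, was at 480 ± 113 CPM in HSC against 339 ± 44.5 CPM in HPC, a log2 change of only 0.50. Camera called both lists higher in HSC, with the larger adjusted p at 0.0017. With an estimated correlation the camera adjusted p was 0.096 for the heme list, which loses its call, and 0.0018 for the other. In HPC too, 12 of 12 heme synthesis genes and 14 of 17 progenitor genes had at least 1 CPM. The erythroid genes rose and fell together over the HSC libraries more than 99.2 percent of 1000 random lists matched on level. A differing share of such cells could give this, but so could genes regulated together within a cell type, so the test does not separate them. In the list tests the estimated correlation was 0.33 for the erythroid genes and 0.77 for ribosomal protein genes. Also, 4 libraries are few for this, and stem cells that themselves express the erythroid genes stay open.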

How the results depend on the processing

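The fits on unique exon reads, main-assembly rows and gene reads, with the share of exon-exon reads, and without both libraries numbered 4 were chosen only after the results were seen. The count of 4733 genes lay between 3412 and 5210 in every setting but 1. Testing against a fold of 1.5 gave 2099 genes, 1296 higher and 803 lower in HSC, as a stricter test must. No gene called in both the main fit and another setting changed direction, except 2 on gene reads. Genes that lost their call were not checked for this. Upper quartile scaling gave 61.7% of calls as higher in HSC, against 52.7%, and moved the median change to 0.08. Leaving out 1 library gave 4184 to 4587 genes and kept 4068 to 4279 of the 4733. The labels do not say what the replicate numbers mark, and the data do not show that all of them pair the samples. Same-numbered libraries had correlations of their deviations of 0.04, −0.18, 0.24 and 0.41, and 4 of 8 libraries, those numbered 3 and 4, correlated best with their own number. The replicate block gave 5036 genes and 17 lists.

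The count of 14 lists was 8 with an estimated correlation (3 higher, 5 lower), with adjusted p of 0.097 for S phase genes, early blood transcription factors and mast cell, basophil and eosinophil markers, 0.36 for interferon-stimulated genes, 0.43 for receptor genes and 0.34 for red cell markers. It was 22 with fry (12 higher), which asks whether a list's genes move on balance and compares them with no other genes. Fry added cholesterol synthesis (0.00096), autophagy and lysosome (0.00020), antioxidant (0.010), TGF-beta and BMP (0.00083), DNA methylation and Polycomb (0.0046), B cell (0.0014), T and NK cell (0.010) and monocyte (0.013) lists. Under voom with quality weights 10 lists were higher. It added immediate early (0.048), cholesterol synthesis (0.019), antioxidant (0.015) and TGF-beta genes (0.027), and lost sort markers (0.18) and receptor genes (0.24). Antioxidant genes also passed with upper quartile scaling (0.043), no filter (0.036) and the replicate block (0.042), under which immediate early and TGF-beta genes passed at 0.044. Leaving out 1 library gave 0.019 (without HSC replicate 3) to 0.15 for antioxidant genes, which also passed without HPC replicate 4 (0.037), and 0.039 (without HSC replicate 4) to 0.095 for TGF-beta genes. Unique exon reads lost interferon-stimulated genes (0.059), and leaving out both libraries numbered 4 added TGF-beta genes (0.043). The causes were not tested.

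Among the 68 genes named by the rule, 3 changed their call in the settings that kept the threshold of 0.05 and no minimum fold; the threshold of 0.01 and the fold of 1.5 were planned for the count of genes only. Heatr1, at an adjusted p of 0.042 and so also not past 0.01, lost its call with upper quartile scaling, voom, the share of exon-exon reads and in 6 fits that left out 1 library. Kit passed with upper quartile scaling, the replicate block, voom, DESeq2 and without HSC replicate 4, and Lyz2 with no filter, DESeq2, the share of exon-exon reads and without HPC replicate 2 or HSC replicate 2. In 23 cases a value without a call changed sign. Calls of small changes may be limited. In the simulation 35 of 100 changes of 1.5-fold were recovered, but only 200 genes were changed there. With 4733 genes called here, the adjustment lets larger unadjusted p-values pass, so that share does not describe these data. Whether depth, the number of libraries or their spread limits such calls was not tested. Alternatives planned for normalized values were not run, since the files hold counts.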

Other observations

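The 2 further fits of the imprinted list, without Igf2r and on exon reads, were chosen only after the result was seen. Several long noncoding RNAs, read from gene reads because they have no exon counts, were higher in HSC. Meg3, an imprinted noncoding RNA, was at 98.1 ± 15.3 CPM in HSC and 0.359 ± 0.336 CPM in HPC (SD, n = 4 each; edgeR adjusted p = 2.8e-09), or 0.192 CPM without HPC replicate 1. Neat1, which builds nuclear paraspeckles, was at 110 ± 12.2 against 55.1 ± 8.59 CPM, and Malat1 at 3413 ± 426 against 2428 ± 457 CPM. These genes were chosen after their values were seen.

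Imprinted genes are expressed from a single parental copy in at least some tissues. Those noticed higher in HSC were Ndn, Cdkn1c, Grb10, Meg3, H19, Rian, Mirg and Airn. H19 had 288 reads over the 4 HSC libraries and 0 over the HPC libraries, at least 24.3-fold higher against a floor of 3 reads per library. As a hypothesis, the pattern may extend to other imprinted genes, and 41 that were not used to notice it were listed before their values were looked up. Of 31 tested on gene reads, 13 were higher in HSC, 1 was lower and 17 had no call, with a median log2 change of 0.61 (camera p = 0.00054, and p = 0.043 with an estimated correlation). Among them Phlda2 was at 15.6 ± 2.81 against 3.51 ± 0.338 CPM, Dlk1 at 6.73 ± 1.95 against 0.860 ± 0.256 CPM, and Igf2 at least 25.1-fold higher with 0 reads in HPC, while Gnas, Ube3a and Nap1l4 had no call. The call of Igf2r (log2 1.34) is uncertain, since Airn lies within it and its exon reads alone gave −0.02. Without Igf2r 12 of 30 were higher and 1 lower, with a median of 0.58, and on exon reads 11 of 29 were higher and 1 lower, with a median of 0.64, and camera called the list higher in both. Genes of the same imprinted cluster are not independent, and no allele was read here. Further genes tested share a cluster with the genes that prompted the list, as Igf2r does with Airn. Among them are Igf2 with H19, Dlk1 with Meg3, and Phlda2 with Cdkn1c. Only Igf2r was left out, so the test cannot show whether the pattern extends beyond the clusters first noticed. The test is therefore not fully independent of the genes first noticed.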
